A study of Capra hircus with 6 samples.

How the data were processed

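Total RNA was isolated with TRIzol from ovarian follicles of 3 Boer and 3 Macheng black goats and depleted of ribosomal RNA with a Ribo-Zero kit before Illumina library preparation, per the labels' protocols. No RNase R digestion or other enrichment for circular RNA is named there. The breed was taken from the sample titles, which also number the animals. The animal numbers in the sample codes of the labels and files differ from those of the titles in the 3 Boer libraries and Macheng black 3. For Boer 2 the code in the labels differs from that of the file in its last digit, while the breed letters of the codes match the titles in all 6 libraries. Bowtie2 2.0.6 and TopHat2 are named in the submitters' processing notes; the circRNA caller, its thresholds, the genome build and the annotation are not given in the sources used here. Choice of aligner and caller decides which back-splices are found, so absolute numbers of circRNAs hold for these files only.

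The deposited files, 1 per library, list circRNAs with their position, strand, exon and intron parts, spliced length, and 2 columns of whole-number counts: reads on the back-splice junction, used for every comparison, and reads called non-junction reads. None of the deposited counts is normalized, per the file headers and the values. No listed circRNA has under 2 back-splice reads, so a circRNA not listed in a library had 0 or 1 read there, or was not found by the caller; it entered the tests as 0. The spliced length and full length in bases are other deposited values. In all 28870 entries the full length equalled end minus start, so starts count from 0, and 1 was added to print positions counted from 1. In all 28310 entries with an exon or intron part, the spliced length equalled the smaller of the summed parts and the full length, so it is not an exon-only length.

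CircRNAs were matched between libraries by chromosome, start, end and strand, since their identifiers are numbered within each file. The host gene identifiers needed a filter, chosen after the data were seen. Of 829 identifiers, 29 were set aside because they were spread over several chromosomes (14 of them) or had a listed exon or intron over 1 Mb, and these 29 covered 82.3% of the circRNAs. A further 413 circRNAs had no listed part. The 2043 circRNAs (14.6%) with exactly 1 remaining identifier rest on 783 host genes, of which 754 were matched to a symbol by identifier in a table of the goat assembly ARS1.2, used for names only. All results on host genes, usage and gene lists therefore describe a minority of the circRNAs, and classes (exonic or intronic) of the others rest on unusable identifiers. To use every circRNA without host genes, circRNAs that overlap on 1 strand were also merged into 8112 loci, an analysis added after the data were seen.

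The comparisons between breeds were set before the data were examined, with 3 libraries per breed and no block. CircRNAs with at least 2 reads in at least 3 libraries were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with trimmed mean of M-values (TMM) normalization and Benjamini-Hochberg adjustment at 0.05. Library sizes were all listed back-splice reads of a library. Host genes were tested likewise on summed counts, and their CPM are scaled to the reads of host genes, not of all circRNAs. Use of circRNAs within host genes was tested with edgeR's diffSpliceDGE (Simes p per gene), and lists with camera in limma 3.58.1 on voom weights with a preset correlation of 0.01 and at least 5 tested members. CPM are counts scaled to the effective library size after TMM. Log2 fold changes are Boer over Macheng black; their SE was derived from the fold change and the F statistic. Values per library were compared by exact permutation tests in scipy 1.17.1 with Python 3.11.15, and shares in single libraries carry exact (Clopper-Pearson) 95% intervals. Thinning drew 23480 listed reads per library without replacement, 20 times, and circRNAs left with 1 read were then dropped. Macheng black 3, with this total, was kept whole, so thinned libraries were not fully equal in listed reads.

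Named items were fixed by a rule set before the data were examined: the 10 circRNAs with the smallest p in each direction, the 10 with the highest mean CPM, up to 4 tested host genes with the smallest p in each list and any past adjusted p 0.05, the 5 host genes with the smallest p for usage, the 5 in each direction for host genes, and the 5 with the most distinct circRNAs.

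Read totals per library ran from 23480 to 74796, so 1 read was worth between 15.5 and 38.1 CPM after TMM, and differences near these values are not detectable. The biological coefficient of variation was 0.602 for circRNAs and 0.448 for host genes. The tests were checked on simulated counts with 200 changed features. For circRNAs, 9.90% of 4-fold and 53.5% of 16-fold changes were recovered, with 3 false calls among 66. For host genes, 32.6% of 4-fold and 67.6% of 16-fold changes were recovered, with 4 false among 107. For usage, 5 of 22 genes with a 16-fold shift of 1 circRNA were recovered, and for lists the 1 list moved 4-fold. Simulated features were drawn independently of each other, unlike overlapping circRNAs of 1 locus or members of 1 list. These checks therefore do not measure false calls among features that vary together between animals.

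Alternatives were DESeq2 size factors or library totals in place of TMM, DESeq2 1.42.0, no filter or at least 5 reads in 3 libraries, the replicate number as a block, each library left out in turn, and, for values per library, thinning, weighting and a minimum of 2 reads. A robust prior, unlisted circRNAs set to 1 read, sums over loci, and class and length with usable hosts only were added after the data were seen. Leaving out libraries was first run with the filter applied again to the remaining 5; after those counts were seen, the set of tested features was instead held fixed, because a circRNA listed in 1 breed cannot pass with 2 of its libraries. Both versions are given.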

Results

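Circular RNAs (circRNAs), closed molecules formed when a downstream splice site joins an upstream one, were counted in pre-ovulatory ovarian follicles of goats (Capra hircus). Follicles came from 3 Boer goats, a meat breed, and 3 Macheng black goats, and each animal gave 1 library. All animals had received 1000 IU of pregnant mare serum gonadotropin (PMSG), which drives follicle growth, and 500 IU of human chorionic gonadotropin (hCG), which triggers ovulation. The measured value was the number of reads spanning each back-splice junction. The comparison of the 2 breeds addressed which circRNAs of the pre-ovulatory follicle differ between them. Positions are those of the deposited files counted from 1, and the genome build was not given in the sources used here.

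The 6 libraries held 13950 distinct circRNAs and 252857 back-splice reads. The 3 Boer libraries had 74796, 24884 and 41536 reads over 7005, 3538 and 5155 circRNAs. The 3 Macheng black libraries had 39020, 49141 and 23480 reads over 4410, 5415 and 3347 circRNAs. The mean number of circRNAs was 5233 ± 1735 (SD, n = 3) in Boer and 4391 ± 1034 (SD, n = 3) in Macheng black, a difference smaller than the spread between animals (exact permutation test, two-sided, p = 0.6). With 3 animals against 3, this test cannot give a p below 0.1. The back-splice read totals, 47072 ± 25412 and 37214 ± 12926 (SD, n = 3 each), also differed by less than their spread (exact permutation test, two-sided, p = 0.6). Without Boer 1, the library with the most back-splice reads, both differences turned. That in distinct circRNAs per library went to -44.2 and that in back-splice junction reads per library to -4004. After thinning to 23480 reads per library, the numbers of circRNAs were 3285 ± 135 and 3163 ± 181 (SD, n = 3 each, exact permutation test, two-sided, p = 0.4).

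**Figure D1:**
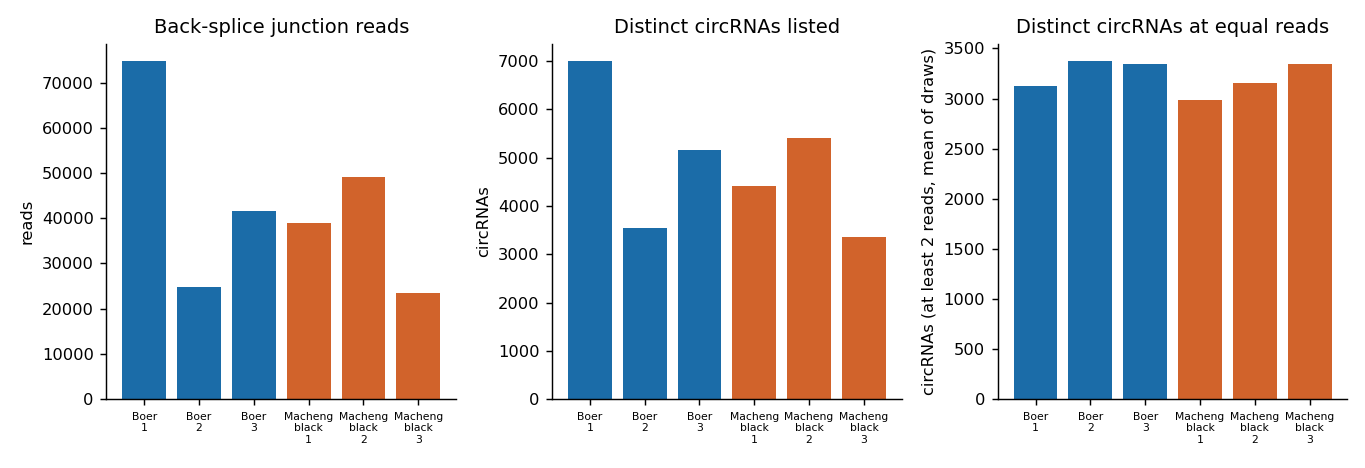
Back-splice junction reads (left), distinct circRNAs listed (middle) and distinct circRNAs with at least 2 reads after thinning each library to 23480 reads (right, mean of 20 draws), 1 bar per library, Boer in blue and Macheng black in orange. The listed numbers run from 3347 to 7005 and follow the reads, while the thinned numbers lie between 2986 and 3376.

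A small set of circRNAs made up most of the signal. The 1132 circRNAs listed in all 6 libraries were 8.11% of the distinct circRNAs and held 63.0% of the reads, while the 8269 listed in 1 library were 59.3% of the circRNAs and held 9.60% of the reads. Boer libraries listed 10136 circRNAs, Macheng black libraries 8563, and 4749 were listed in both breeds. The distance between the ends of a circRNA had a median of 5832 bases, with quartiles of 1817 and 12990. The 10 most abundant circRNAs by mean CPM (read counts scaled to a common library size) included 6 that were abundant in every library. The circRNA at chromosome 24, 40207860 to 40208323, averaged 14344 ± 3171 CPM in Boer and 13869 ± 3226 CPM in Macheng black (SD, n = 3 each). Those at chromosome 7, 12693629 to 12694180, and chromosome 1, 144014343 to 144015556, averaged 8412 ± 2696 and 8499 ± 1330 CPM in Boer and 10479 ± 2054 and 10155 ± 1024 CPM in Macheng black (SD, n = 3 each). Those at chromosome 10, 10338566 to 10342667, and chromosome 1, 146132688 to 146136588, averaged 9745 ± 2368 and 9281 ± 4610 CPM in Boer and 8258 ± 1117 and 8018 ± 2121 CPM in Macheng black (SD, n = 3 each). At chromosome 15, the circRNA from 27869239 to 27870107 averaged 8145 ± 1408 and 8433 ± 3309 CPM (SD, n = 3 each). The deposited annotation placed these 6 in introns without a usable host gene, and none of the 6 passed the edgeR test, with fold changes from -0.32 to 0.24 on the log2 scale.

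The other 4 of the most abundant circRNAs varied widely between animals. Of these, 3 overlap on the minus strand of chromosome 23, in a locus of 13 circRNAs from 24338001 to 24405648. The circRNA from 24338001 to 24381470, the most abundant of all by mean CPM, had 2201 reads in Macheng black 1, 323 in Macheng black 3 and 545 in Boer 2, and was not listed in the other 3 libraries. A second, from 24338001 to 24362056, had 41, 362 and 489 reads in the Boer libraries and 1476, 187 and 141 in the Macheng black libraries. Another, from 24341626 to 24383772, had 1742 reads in Macheng black 1 and was listed in no other library, so it did not enter the test. The whole locus took 15.2% of the back-splice reads of Macheng black 1 and between 0.0548% and 3.83% in the other 5. Neither of the tested pair passed the edgeR test (log2 fold changes of -1.99 ± 1.32 and -1.05 ± 0.76, SE). Without Macheng black 1 these values turned to 0.014 and 0.78, and with no filter on low counts the first of the pair passed (edgeR adjusted p = 0.0482). The remaining one, a circRNA of LOC106501751, is described with the host genes.

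**Figure D2:**
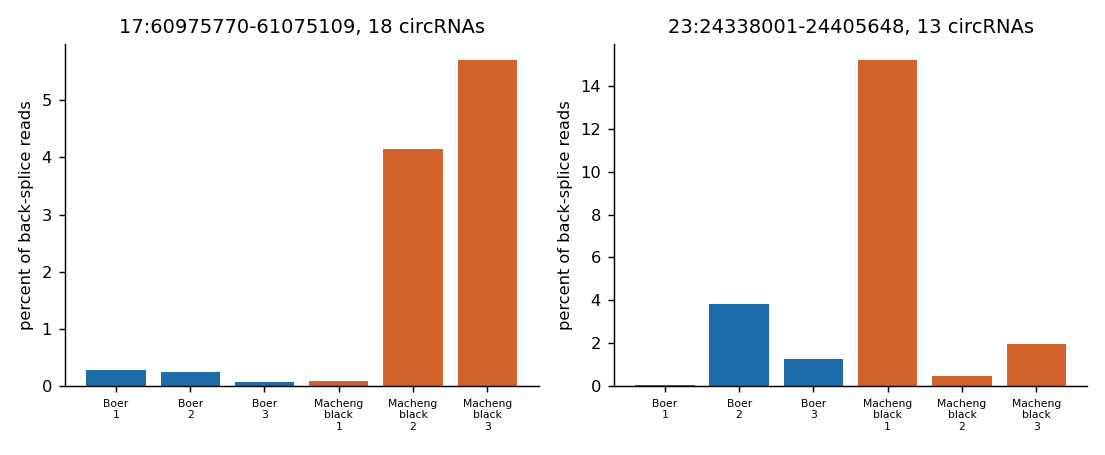
Percent of each library's back-splice reads from 2 loci of overlapping circRNAs, at chromosome 17 (left) and chromosome 23 (right), 1 bar per library, Boer in blue and Macheng black in orange. At chromosome 17, Macheng black 2 and 3 had 4.15% and 5.70% and the other 4 libraries 0.0698% to 0.277%, and at chromosome 23 Macheng black 1 had 15.2%.

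By the deposited exon and intron lists, most circRNAs were classed as intronic in both breeds. The share of back-splice reads from circRNAs with listed introns only was 86.6% ± 0.374 in Boer and 86.7% ± 1.92 in Macheng black (SD, n = 3 each; exact permutation test, two-sided, p = 1.0). The difference in the share of reads from intronic circRNAs, -0.132 points, turned to 0.968 without Macheng black 1 and to 0.0242 without Boer 3. As a share of distinct circRNAs, it was 86.9% ± 0.232 in Boer and 86.4% ± 0.0945 in Macheng black (SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest possible), with each Boer library above each Macheng black library. By share of reads, single libraries ranged from 85.4% in Macheng black 2 (exact 95% interval 85.0% to 85.7%) to 88.9% in Macheng black 1 (88.6% to 89.2%). Such intervals cover counting error only. This share rests on an annotation in which 82.3% of the circRNAs carried a gene identifier that could not be used. By the class counts, all or nearly all circRNAs with such an identifier were listed with introns only. The intronic share therefore mostly counts circRNAs with an unusable identifier. Neither the share nor its difference between the breeds can be read as a measure of origin in introns. Among circRNAs with a usable host gene, the intronic share was 28.5% ± 0.876 in Boer and 29.2% ± 3.03 in Macheng black (SD, n = 3 each; exact permutation test, two-sided, p = 0.9). Of these 2043 circRNAs, 70.0% had a listed exon, and their median span was 7205 bases, against 5131 bases for those with introns only.

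The number of listed exons per circRNA averaged 0.188 ± 0.00160 in Boer and 0.195 ± 0.00191 in Macheng black (SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest this design allows). This low mean follows from the many circRNAs without a listed exon; with a usable host gene it was 1.17 ± 0.0241 and 1.17 ± 0.0107, with the higher mean in Boer (SD, n = 3 each; exact permutation test, two-sided, p = 0.9). Weighting by reads also turned the direction, to a difference of 0.00420 exons. The median spliced length, which in these files is the smaller of the summed exon and intron parts and the full span, averaged 6537 ± 437 bases in Boer and 6165 ± 399 bases in Macheng black (SD, n = 3 each; exact permutation test, two-sided, p = 0.4). Weighting by reads turned this difference to -203 bases.

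Several genes gave rise to many circRNAs. HMCN1, which encodes the matrix protein hemicentin, hosted 25 distinct circRNAs, ARHGAP10 hosted 23, and CEP112, which encodes a centrosomal protein, 19. MED17, a subunit of the Mediator complex, hosted 16, and SENP6, a SUMO protease, 14. Of the 783 usable host genes, 355 had 1 circRNA and 103 had 5 or more. Summed over their circRNAs, HMCN1, CEP112, MED17 and SENP6 did not pass the test between breeds, with log2 fold changes between -0.52 and 0.38; ARHGAP10 did and is described with the host genes.

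In the comparison of single circRNAs, 13 of 3712 tested differed between the breeds, 4 higher in Boer and 9 higher in Macheng black. The circRNA at chromosome 24, 37557366 to 37576786, had 71, 77 and 28 reads in the Macheng black libraries and was not listed in any Boer library, so its level was at least 64.7-fold higher in Macheng black, with Boer set at 1 read per library or 3 over the group (edgeR quasi-likelihood test, adjusted p = 1.04e-08). At chromosome 1, the circRNA from 149011251 to 149063500 had 14, 11 and 12 reads in Macheng black and was not listed in Boer, at least 14.9-fold higher (adjusted p = 0.00352); Boer 2 had 6 reads of a circRNA with both ends moved by 16 bases. Summed with that circRNA, the locus no longer passed (edgeR adjusted p = 0.434), with a 4.88-fold higher mean in Macheng black and Boer 2 at 226 CPM against 229 CPM in Macheng black 2. At chromosome 16, the circRNA from 57786278 to 57822288 had 40, 7 and 14 reads in Boer and was not listed in Macheng black, at least 13.5-fold higher in Boer (adjusted p = 0.00261). At the same locus, the circRNA from 57803816 to 57822288 averaged 573 ± 216 CPM in Boer and 93.1 ± 32.4 CPM in Macheng black (SD, n = 3 each; edgeR adjusted p = 0.0194), with each Boer library above each Macheng black library. On chromosome 4, the circRNA from 84056421 to 84074850 averaged 3718 ± 546 and 819 ± 157 CPM, 4.54-fold higher in Boer (SD, n = 3 each; edgeR log2 fold change 2.18 ± 0.43, SE, adjusted p = 0.00581), again without overlap between the breeds. These circRNAs were annotated as intronic without a usable host gene, a class given to all or nearly all circRNAs with an unusable gene identifier. Of 14 alternatives, 10 kept the call at chromosome 1, 11 and 8 those at chromosome 16 in the order given, and 13 that on chromosome 4, with each of these calls lost without Boer 2 (tested set held fixed). That from 57803816 to 57822288 was also lost with DESeq2, at least 5 reads in 3 libraries, and without Boer 1, Macheng black 1 or Macheng black 2. The loss without Boer 2 depended on the tested set. With the filter applied again, the calls at chromosome 1, chromosome 4 and 57803816 to 57822288 passed without Boer 2 (edgeR adjusted p = 0.00445, 0.00445 and 0.00688). The circRNA from 57786278 to 57822288 then left the test.

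The fourth circRNA higher in Boer lies in introns of ARHGAP10, at chromosome 17, 10078703 to 10108351. It averaged 638 ± 83.2 CPM in Boer and 66.4 ± 58.7 CPM in Macheng black, 9.61-fold higher (SD, n = 3 each; edgeR log2 fold change 3.10 ± 0.61, SE, adjusted p = 0.00581). This call was lost in 4 of 14 alternatives, with DESeq2, at least 5 reads in 3 libraries, and without Boer 1 or Boer 2 (tested set held fixed). With the filter applied again, it passed without Boer 2 (edgeR adjusted p = 0.00445). All 10 tested circRNAs of ARHGAP10 had positive log2 fold changes, from 1.09 to 6.26, though the other 9 did not pass on their own. The most abundant of them, singled out after its values were seen, ran from 9988192 to 10015046, held 72.3% of the gene's reads and averaged 11133 ± 3144 and 4279 ± 1643 CPM (SD, n = 3 each; edgeR adjusted p = 0.721). Another 4 shared its first position, of which the circRNAs ending at 10040261 and 10008564 averaged 1154 ± 460 and 758 ± 177 CPM in Boer and 344 ± 56.2 and 248 ± 119 CPM in Macheng black (SD, n = 3 each; edgeR adjusted p = 0.0652 and 0.242). The circRNA from 10008477 to 10044368 had 13, 7 and 11 reads in Boer and was not listed in Macheng black (edgeR adjusted p = 0.139).

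**Figure D3:**
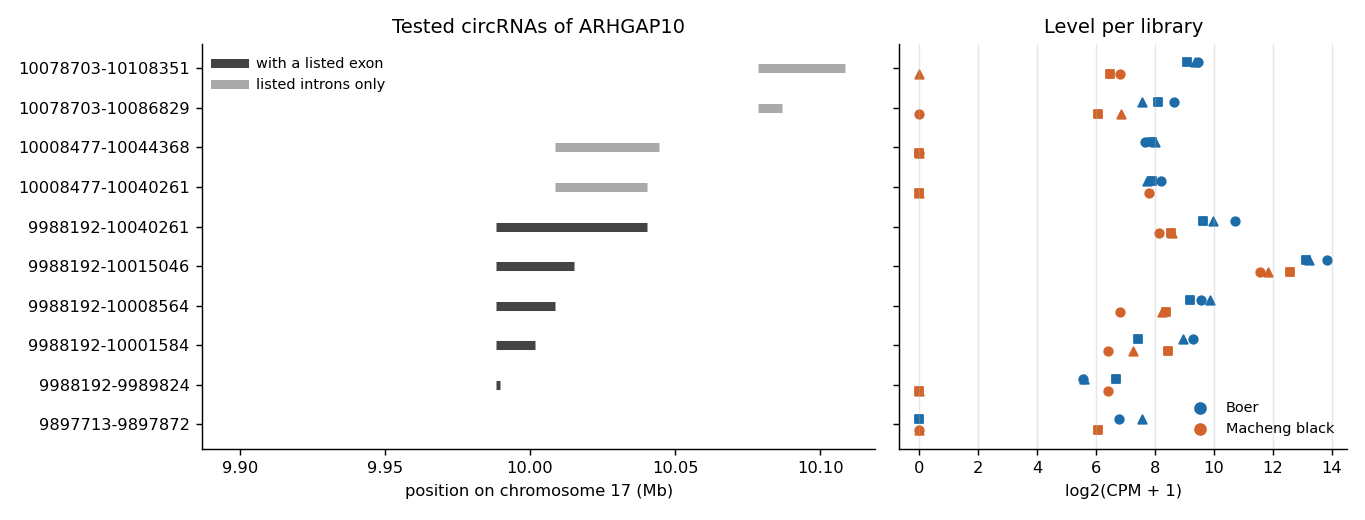
The 10 tested circRNAs of ARHGAP10 on chromosome 17 (left, bars to scale in Mb, dark with a listed exon and grey with introns only) and their levels as log2(CPM + 1) in each library (right, Boer in blue, Macheng black in orange, with circles, squares and triangles for replicates 1, 2 and 3). A point at 0 is a circRNA that was not listed in that library. The circRNA from 10078703 to 10108351 averaged 638 CPM in Boer and 66.4 CPM in Macheng black.

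Of the 9 circRNAs higher in Macheng black, 6 overlap on the minus strand of chromosome 17, in a locus of 18 circRNAs from 60975770 to 61075109. The most abundant, from 60996146 to 61045393, had 892 and 654 reads in Macheng black 2 and 3, 11 in Macheng black 1 and 70, 31 and 0 in the Boer libraries (edgeR log2 fold change -4.38 ± 0.94, SE, adjusted p = 0.0155). The other 5, from 60996146 to 61031371, 60997112 to 61031551, 60996034 to 61029927, 60994251 to 61041283 and 60997112 to 61045573, had log2 fold changes from -4.69 to -3.15 and edgeR adjusted p from 0.00198 to 0.011. In each of the 6, Macheng black 1 lay within the range of the Boer libraries or below it, so that the difference rests on Macheng black 2 and 3. All 6 calls ended with at least 5 reads in 3 libraries, without Boer 2 (tested set held fixed) and with a robust prior, which was added after the data were seen. Of 14 alternatives, 7 kept the call of the most abundant and 10, 9, 9, 7 and 7 those of the other 5, in the order above. The most abundant was also lost with DESeq2, with the replicate block and without Boer 1 or Macheng black 3. DESeq2 also ended the calls from 60996146 to 61031371, 60994251 to 61041283 and 60997112 to 61045573. Without Boer 1, only the call from 60996146 to 61031371 remained. Over the alternatives, the log2 fold change of the most abundant ranged from -4.95 to -3.75, and those of the other 5, in the order above, from -9.34 to -3.90, -4.36 to -2.62, -3.93 to -2.60, -3.71 to -2.36 and -4.93 to -3.25. The remaining circRNA, at chromosome 20, 56016142 to 56017532, had 16, 34 and 4 reads in Macheng black and 0, 0 and 2 in Boer (edgeR log2 fold change -4.68 ± 0.91, SE, adjusted p = 0.00581). Its log2 fold change ranged from -7.21 to -3.92 over 13 alternatives, of which 9 kept the call. The call was lost with DESeq2 and without Boer 1, Boer 2 or Macheng black 2 (tested set held fixed). With the filter applied again, it passed without Boer 2 (edgeR adjusted p = 0.00807).

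**Figure D4:**
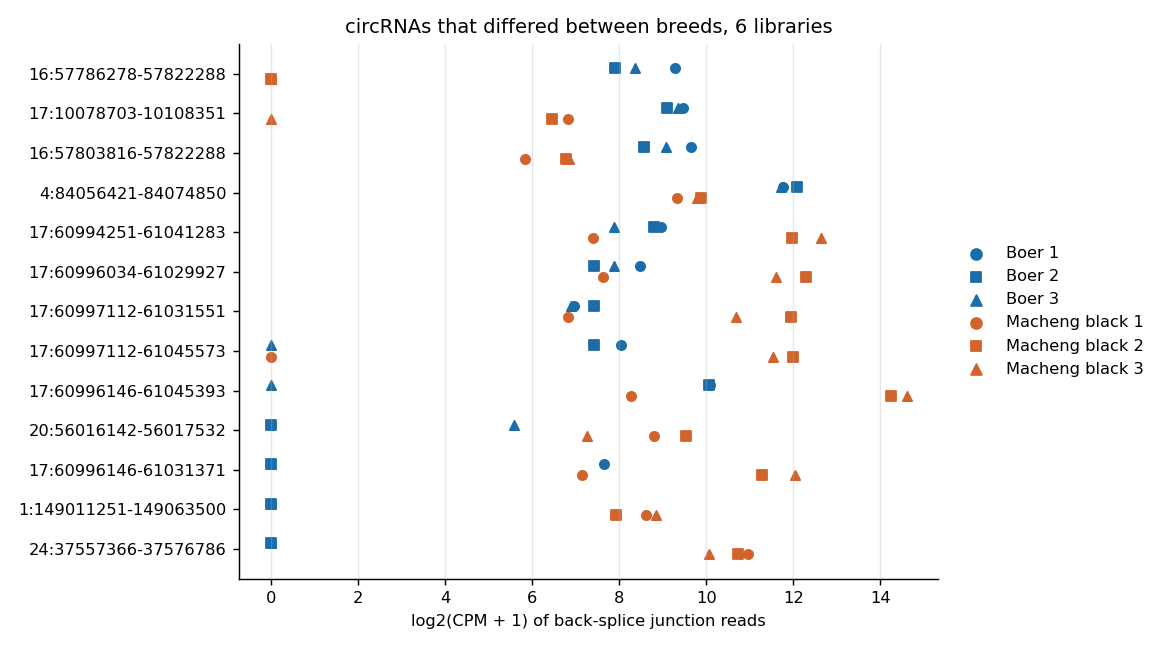
Levels, as log2(CPM + 1), of the 13 circRNAs that passed adjusted p 0.05, 1 row per circRNA named by chromosome, start and end, and 1 point per library (Boer in blue, Macheng black in orange, with circles, squares and triangles for replicates 1, 2 and 3). A point at 0 is a circRNA that was not listed in that library. In the 6 rows of chromosome 17 from 60994251 to 61045573, Macheng black 2 and 3 lie above the other 4 libraries.

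Of the first 10 circRNAs by p in each direction, 7 did not pass, 3 of them circRNAs of ARHGAP10 given above. The others with larger means in Boer were a circRNA of PAWR, which encodes a pro-apoptotic protein, at chromosome 5, 8725155 to 8758770 (862 ± 641 and 174 ± 58.6 CPM, SD, n = 3 each; edgeR adjusted p = 0.0911), and those at chromosome 11, 37465851 to 37470954 (850 ± 173 and 275 ± 88.3 CPM; adjusted p = 0.139), and chromosome 10, 69042961 to 69055364 (575 ± 406 and 150 ± 57.6 CPM; adjusted p = 0.249). With a larger mean in Macheng black, it was the circRNA at chromosome 22, 48127096 to 48131864 (185 ± 39.8 and 809 ± 579 CPM, SD, n = 3 each; edgeR adjusted p = 0.0597), which passed in 7 of 14 alternatives and had 1451 CPM in Macheng black 1 against 328 and 647 in Macheng black 2 and 3. Those of PAWR, chromosome 11 and chromosome 10 passed in 6, 1 and 1 of 14. At an unadjusted p under 0.05 there were 194 circRNAs, against 185.6 expected by chance, and DESeq2 made 8 calls. With the tested set held fixed, 4 circRNAs passed without Boer 1 (3 of the 13 among them), 1 without Boer 2 (also of the 13) and 21 without Macheng black 1 (12 of the 13). With the filter applied again to the 5 remaining libraries, the counts without Boer 1, Boer 2 and Macheng black 1 were 4, 15 and 15, and those without Macheng black 2 and 3 were 0 and 4. The circRNA at chromosome 24, 37557366 to 37576786, passed in each of the 14 alternatives that kept it among the tested circRNAs, but it leaves the test when a Macheng black library is left out and the filter is applied again.

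All 3 Boer libraries and no Macheng black library listed 64 circRNAs, and all 3 Macheng black libraries and no Boer library listed 35. After thinning to 23480 reads per library these numbers were 47.8 and 42.6. The 3 libraries with the most back-splice reads (Boer 1, Boer 3 and Macheng black 2) shared 258 circRNAs that the other 3 lacked.

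Summed per host gene, 5 of 434 tested genes differed, 4 higher in Boer and 1 in Macheng black. ARHGAP10 was 2.84-fold higher in Boer, at 90369 ± 19357 against 31864 ± 9825 CPM of host gene reads (SD, n = 3 each; edgeR adjusted p = 0.0354), with each Boer library above each Macheng black library. PAWR was 2.73-fold higher, at 6958 ± 4178 against 2550 ± 671 CPM, and CRB1, which encodes a cell polarity protein, was 2.68-fold higher, at 6294 ± 966 against 2353 ± 634 CPM (SD, n = 3 each; edgeR adjusted p = 0.0354 for both). The circRNAs of PAWR lie on chromosome 5, 8718889 to 8758770, and those of CRB1 on chromosome 16, 73964669 to 73972385. The breeds did not overlap in CRB1, while in PAWR Boer 1 lay below Macheng black 2 and 3. CLPTM1, on an unplaced scaffold, had 15, 13 and 22 reads in Boer and 0, 0 and 6 in Macheng black (edgeR log2 fold change 2.60 ± 0.74, SE, adjusted p = 0.038). With its Macheng black reads in 1 library, this value ranged from 1.90 to 7.15 over 13 alternatives, of which 4 kept the call. LOC106501751, a gene with no descriptive symbol, was 6.09-fold higher in Macheng black (edgeR log2 fold change -2.60 ± 0.42, SE, adjusted p = 3.26e-07). It averaged 16546 ± 2234 CPM in Boer and 100740 ± 75840 CPM in Macheng black (SD, n = 3 each). Macheng black 1, at 15214 CPM, lay within the Boer range of 14655 to 19011 CPM, so the difference rests on Macheng black 2 and 3. The call was lost with DESeq2, at least 5 reads in 3 libraries, the replicate block and a robust prior. It was also lost without Macheng black 3 (tested set held fixed). Nearly all reads of LOC106501751 came from 1 exon-containing circRNA at chromosome 29, 48241251 to 48265156. This circRNA had 1310 and 529 reads in Macheng black 2 and 3, 93 in Macheng black 1 and 230, 67 and 116 in Boer. On its own this circRNA missed the threshold (edgeR adjusted p = 0.0657) and passed in 7 of 14 alternatives.

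Of the first 5 host genes by p in each direction, 5 did not pass. NBEA, which encodes the trafficking protein neurobeachin, averaged 5360 ± 1029 and 2010 ± 910 CPM (SD, n = 3 each; edgeR adjusted p = 0.0532). CDK8, a kinase of the Mediator complex, and CNOT6, a deadenylase of the CCR4-NOT complex, averaged 285 ± 289 and 771 ± 673 CPM in Boer and 1931 ± 333 and 2873 ± 365 CPM in Macheng black (SD, n = 3 each; edgeR adjusted p = 0.0937 for both). LOC102172654 averaged 165 ± 286 and 1868 ± 1513 CPM (SD, n = 3 each; edgeR adjusted p = 0.0937), and FOXN3, a forkhead transcription factor, 3830 ± 563 and 7542 ± 4779 CPM (SD, n = 3 each; edgeR adjusted p = 0.171). There were 32 genes at an unadjusted p under 0.05, against 21.7 expected by chance. DESeq2 called 1 gene, and 0 genes passed in edgeR with at least 5 reads in 3 libraries or with the replicate number as a block. With the tested set held fixed, there were 4, 1 or 2 calls without Boer 1, 2 or 3 (3, 1 and 1 of them among the 5) and 1, 3 or 1 without Macheng black 1, 2 or 3 (1, 2 and 1 among the 5); with the filter applied again there were 2, 1 or 1 and 1, 0 or 0. Of 13 alternatives, 8 kept the call of LOC106501751, 6 that of ARHGAP10, 4 those of PAWR and CLPTM1 and 3 that of CRB1.

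The share of each circRNA within its host gene was tested in 121 genes with 358 circRNAs, and no gene passed (edgeR, 3 genes at an unadjusted p under 0.05). The gene with the smallest p was MED17 (edgeR adjusted p = 0.912), whose circRNA at chromosome 29, 520898 to 535213, had 19, 13 and 4 reads in Boer and 2, 2 and 0 in Macheng black. ITCH, a ubiquitin ligase, followed with a circRNA at chromosome 13, 61854918 to 61893416, listed in Macheng black alone with 5, 4 and 4 reads. KAT2B, a histone acetyltransferase, had such a circRNA at chromosome 1, 154740553 to 154757624, with 6, 4 and 3 reads, and PAN3, a deadenylase subunit, at chromosome 12, 29624243 to 29636928, with 3, 5 and 2 reads. In SEC23IP the circRNA at chromosome 26, 38428786 to 38443320, had 9, 2 and 2 reads in Boer and was not listed in Macheng black. These 4 genes had an edgeR adjusted p of 0.912 each.

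Of 19 gene lists fixed before the data were examined, 5 had at least 5 tested host genes, and none of the 5 differed between the breeds (camera, 1 list at an unadjusted p under 0.05). The hosts of widely described circRNAs came closest, without passing (5 tested members, 3 with a positive log2 fold change and SMARCA5 and ITCH with a negative one; camera p = 0.0212, adjusted p = 0.106; adjusted p = 0.483 with an estimated correlation). Of its members, 1 passed both over all genes and adjusted over the list alone, ARHGAP10 (edgeR adjusted p = 0.00113 over the list). SLC8A1, a sodium-calcium exchanger, averaged 30067 ± 3711 and 19316 ± 3412 CPM, CAMSAP1, a microtubule minus-end protein, 13156 ± 2400 and 9438 ± 764 CPM, and SMARCA5, a chromatin remodelling ATPase, 20676 ± 7285 and 31057 ± 6909 CPM in Boer and Macheng black (SD, n = 3 each).

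In the other 4 tested lists, 0 members passed in edgeR, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. TGF-beta, BMP and activin signalling had 5 tested members (camera adjusted p = 0.475; adjusted p = 0.554 with an estimated correlation), with log2 fold changes of -0.50 ± 0.46 for the receptor TGFBR2, 0.60 ± 0.56 for the signal transducer SMAD1, -1.08 ± 1.49 for the receptor BMPR1A and -0.57 ± 1.21 for the ligand BMP6 (SE). Extracellular matrix and basal lamina had 5 (adjusted p = 0.640), with 0.70 ± 0.51 for COL12A1, 0.73 ± 0.78 for LAMC1, -0.32 ± 0.51 for COL14A1 and 0.55 ± 1.90 for FBLN1. Chromatin remodelling and histone modification had 7 (adjusted p = 0.891), with a median log2 fold change of -0.09 and a mean of 0.20, and 1.26 ± 0.76 for the demethylase KDM5B, 0.34 ± 0.35 for the methyltransferase EHMT1 and -0.36 ± 0.52 for the acetyltransferase CREBBP. Ubiquitin ligases and deubiquitinases had 7 (adjusted p = 0.475), with 1.49 ± 0.86 for UBE3C, 0.73 ± 0.48 for UBE3A, -0.50 ± 0.50 for ITCH and 0.98 ± 1.75 for FBXW11.

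The other 14 lists held too few tested hosts for a test. Steroidogenesis and cholesterol handling had 3, with log2 fold changes of 0.51 ± 0.60 for OSBPL8, 0.61 ± 0.94 for NR5A2 and -0.69 ± 1.79 for SRD5A1 (SE). Hippo signalling had 2, NF2 (-1.76 ± 1.58) and STK4 (-0.29 ± 1.02), granulosa cell markers had 2, HTRA1 (1.73 ± 1.62) and NR5A2, and factors acting on circRNA formation had 2, DHX9 (1.03 ± 1.93) and SRSF1 (0.21 ± 0.62). Insulin, IGF, PI3K and FOXO signalling had 1, TSC1 (0.45 ± 1.86), and apoptosis and atresia had 1, MDM4 (-1.58 ± 1.86). None of these genes passed the edgeR test, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The sign of the log2 fold change turned when a single library was left out for NR5A2, TSC1, STK4, SRSF1, COL12A1, COL14A1 and FBLN1. No usable host with a listed circRNA was found among the genes of ovulation and cumulus expansion or the oocyte markers. The gonadotropin, prolactin and steroid receptors, the endothelial, leukocyte, theca and stromal lists and the cell cycle list had 1 such host each, and the smooth muscle and pericyte markers 2, all below the read minimum.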

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

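The tests in this part were chosen after the results were seen. No group had the 4 or more libraries needed to test for outlying samples, and the design holds 1 contrast. The column of non-junction reads, which no comparison used, held 16624659 reads over the 6 libraries, a signal outside the main measurement. Over 1117 circRNAs listed in every library with such reads, the median circRNA had 240, 275 and 254 non-junction reads in the Boer libraries and 255, 258 and 315 in the Macheng black libraries. Back-splice reads made up a median of 9.13%, 2.65% and 4.72% of both kinds in Boer and 3.70%, 5.21% and 2.16% in Macheng black (exact permutation test of the means, two-sided, p = 0.6). The libraries thus differed more in back-splice reads, with medians from 7 to 22, than in non-junction reads at the same circRNAs. How the authors assigned non-junction reads is not given in the sources used here.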

How the results depend on the processing

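The robust prior, unlisted circRNAs set to 1 read, sums over loci, usable hosts only and the filter applied again were chosen after the results were seen, and the tested set was held fixed on leaving out libraries only after the counts with the filter applied again had been seen. For circRNAs differing between breeds (13), DESeq2 gave 8 (6 of the 13 among them), no filter 35, at least 5 reads in 3 libraries 2 and unlisted circRNAs set to 1 read 22, while DESeq2 size factors gave 16, library totals 17, the replicate block 11, the robust prior 18 (7 of the 13) and loci 10. Leaving out 1 library gave 1 to 21 with the tested set held fixed, and with the filter applied again 4, 15 and 12 without Boer 1, 2 and 3 and 15, 0 and 4 without Macheng black 1, 2 and 3. For host genes differing between breeds (5), DESeq2 gave 1, no filter 3, at least 5 reads in 3 libraries 0, the replicate block 0 and the robust prior 3, and both other normalizations 5. Leaving out 1 library gave 1 to 4, and with the filter applied again 2, 1 and 1 without Boer 1, 2 and 3 and 1, 0 and 0 without Macheng black 1, 2 and 3. The cause of these changes was not tested. Usage kept 0 calls in edgeR under its 9 alternatives. Gene lists differing between breeds ranged from 0 to 1, the 1 being the list hosts of widely described circRNAs without Macheng black 2 (camera adjusted p = 0.046, with adjusted p from 0.046 to 0.483 over its alternatives). The replicate numbers come from different animals, and the correlations of libraries with the same number, after removal of the breed means, were -0.03, -0.04 and 0.01, so that no pairing was used.

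Of values per library, the difference (Boer minus Macheng black) in distinct circRNAs per library, 842, ranged from -44.2 to 1689 on leaving out 1 library, and was 122 after thinning. That in back-splice junction reads per library, 9858, ranged from -4004 to 20952. The share of reads from intronic circRNAs differed by -0.132 points, by 0.494 as a share of distinct circRNAs, and by -0.791 to 0.968 on leaving out 1 library. Listed exons per circRNA differed by -0.00612, by 0.00420 weighted by reads and by 0.00760 with usable host genes. The median spliced length per circRNA differed by 372.5 bases and by -203 weighted by reads. The cause was not tested. A minimum of 2 reads moved nothing, since no listed circRNA has fewer.

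Of the single circRNAs, host genes (levels and usage) and lists named, 873 values under the alternatives kept their direction and side of the threshold, 97 no longer passed, 31 passed anew and 28 changed sign, the cause of which was not tested. Written as chromosome, start, end and strand, circRNA 24_40207860_40208323_- (0.05) was at -0.020 with DESeq2 size factors, -0.022 with DESeq2, -0.030 with unlisted circRNAs set to 1 read and -0.090 to 0.27 on leaving out 1 library. Likewise, circRNA 15_27869239_27870107_- (-0.05) was at 0.017 with no filter, 0.020 with the replicate block and -0.30 to 0.28 on leaving out 1 library. MED17 (-0.02) was at 0.011 with no filter and -0.087 to 0.12 on leaving out 1 library. On leaving out 1 library, log2 fold changes ranged from -13.05 to 0.014 and -1.49 to 0.78 for the pair at chromosome 23, from -0.24 to 0.49 at chromosome 1, 146132688 to 146136588, from -0.15 to 1.05 for COL12A1, -0.55 to 1.30 for NR5A2, -0.16 to 3.35 for TSC1, -0.68 to 0.19 for STK4, -0.22 to 3.69 for FBLN1, -0.10 to 0.42 for SRSF1 and -0.81 to 0.54 for COL14A1. The list of chromatin remodelling and histone modification turned without Boer 3 and Macheng black 2 (camera adjusted p = 0.822 and adjusted p = 0.823), with adjusted p from 0.472 to 0.910 on leaving out 1 library. Without a change of sign, the log2 fold change moved by over 1.5 times as a fold for further items. It ranged from 0.37 to 5.15 for HTRA1, 0.39 to 4.74 for FBXW11, 0.27 to 3.69 for DHX9, -4.97 to -0.55 for BMPR1A, -3.69 to -1.14 for MDM4, -3.83 to -0.22 for SRD5A1, -6.41 to -2.22 for LOC102172654, -3.41 to -2.08 for CDK8, 0.39 to 2.30 for KDM5B and 0.37 to 1.39 for LAMC1 over the alternatives. For circRNAs it ranged from -9.30 to -6.08 at chromosome 24, 37557366 to 37576786, 3.62 to 7.37 at chromosome 16, 57786278 to 57822288, -7.07 to -3.94 at chromosome 1, 149011251 to 149063500, -2.50 to -1.38 at chromosome 22, 48127096 to 48131864, -3.09 to -1.98 at chromosome 29, 48241251 to 48265156, and 2.83 to 6.38 at chromosome 17, 10008477 to 10044368.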

Other observations

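The locus analysis and the tests of explanations were chosen after the patterns they address were seen. Only for the first test of a wrong breed label and that of equal depth for the shared circRNAs were the values tested not yet known. Summing circRNAs that overlap on 1 strand, 10 of 2934 tested loci differed between the breeds, 3 higher in Boer and 7 higher in Macheng black (edgeR, 187 at an unadjusted p under 0.05 against 146.7 expected by chance). A locus of 8 circRNAs at chromosome 19, 13651450 to 13676607, in which no single circRNA passed, had 0, 2 and 0 reads in Boer and 10, 41 and 15 in Macheng black (edgeR log2 fold change -5.00 ± 0.85, SE, adjusted p = 0.000133). A locus of 6 circRNAs at chromosome 10, 69015269 to 69096171, had 55, 5 and 66 reads in Boer and 3, 10 and 5 in Macheng black (log2 fold change 2.36 ± 0.52, SE, edgeR adjusted p = 0.00919), so that Boer 2 lay near Macheng black. The locus of 10 circRNAs at chromosome 16, 57780433 to 57822288, was 6.59-fold higher in Boer (edgeR adjusted p = 7.08e-05), and the single circRNA at chromosome 22, 48127096 to 48131864, passed as a locus (edgeR adjusted p = 0.0166) though not as a circRNA, with the same reads. Other calls were lost: the locus at chromosome 1, 149011251 to 149063516, had an edgeR adjusted p of 0.434, and those of the host genes ARHGAP10 and CRB1 had 0.104 each, PAWR 0.218 and CLPTM1 0.376. For these 4 the log2 fold changes hardly moved. They were 1.49 ± 0.41, 1.41 ± 0.38, 1.40 ± 0.41 and 2.59 ± 0.85 (SE) as loci, and 1.40 ± 0.39, 1.40 ± 0.38 and 2.60 ± 0.74 as host genes for the last 3. The edgeR unadjusted p rose, to 0.000546, 0.000481, 0.00126 and 0.00339 as loci from 0.000226, 0.000326, 0.000269 and 0.000437 as host genes. The adjustment also ran over 2934 loci against 434 host genes. How far each of these ended the calls was not tested. The locus counts were not run under the other alternatives.

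With 3 libraries in each breed there are 10 splits of the libraries, too few for a share under 0.05. The breeds gave 13 differing circRNAs and the highest other split 16, with 2 of the 10 splits at 13 or more. That other split set Boer 1, Macheng black 2 and Macheng black 3 against the rest, and 9 of its 16 circRNAs lay in the chromosome 17 locus from 60975770 to 61075109, against 6 of the 13 by breed. For host genes the breeds gave 5 and the highest other split 3 (1 split at 5 or more), and for loci 10 and 8 (1 split at 10 or more). For usage in edgeR the breeds gave 0 and the highest other split 1, and for lists 0 and 0 (10 of the 10 splits as large in each). For circRNAs listed in all of 1 side and none of the other, the breeds gave 99 and the highest other split 266 (4 of the 10 splits at 99 or more).

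The 3 differing circRNAs listed in every library of 1 breed and in no library of the other lie at chromosome 24, 37557366 to 37576786, chromosome 1, 149011251 to 149063500, and chromosome 16, 57786278 to 57822288. At the rate of the breed that had them, at least 42.6 reads would have been held by the other. They were chosen by a test already scaled to library size, so this number adds no separate evidence on lower depth. A called position shifted by up to 20 bases had 0 reads in 8 of the 9 pairs of circRNA and library, which argues against a shift there, but at chromosome 1 it had 6 reads in Boer 2, within the 5 to 17 expected, so a shift may account for that library, and the summed locus did not pass (edgeR adjusted p = 0.434). At chromosome 16, the 8 other circRNAs of the locus that were not called were also lower in Macheng black when summed (log2 fold change 1.75 ± 0.64, SE, edgeR unadjusted p = 0.00931 by the quasi-likelihood test), with 284 CPM in Macheng black 2 against 342 to 680 CPM in Boer, so a lower output of the locus may account for part of that absence; whether it accounts for all could not be told apart, since the edgeR unadjusted p against the upper limit of 3.13 for the rest was 0.000941 with unlisted circRNAs at 0 reads and 0.0945 at 1 read. Sequence differences between the breeds and the reference remain open and were not tested, as no genome sequence was at hand, as does a difference in biology between the breeds.

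At the chromosome 17 locus from 60975770 to 61075109, Macheng black 1 had 33 reads against 2037 and 1338 in Macheng black 2 and 3, for which lower depth cannot account, as 1563 reads would be expected at the lower rate of the other pair. A wrong breed label of Macheng black 1 could not be told apart from a difference between animals: of 159 circRNAs listed in Macheng black 2 and 3 and not in Boer 1 and 2, it listed 30.8% (exact 95% interval 23.7% to 38.6%) and Boer 3 24.5% (18.1% to 32.0%), and these intervals overlap. Of 310 circRNAs listed in Boer 1 and 2 and not in Macheng black 2 and 3, it listed 34.8% and Boer 3 41.9%, also in the direction of the labels with overlapping intervals. The next check used circRNAs called in the other 5 libraries alone, 1 per locus and without this locus. Macheng black 1 lay nearer to its breed at 4 of 7 loci (exact 95% interval 18.4% to 90.1%). These included chromosome 4 and chromosome 16, and it lay nearer to Boer at the others. Treated alike, Boer 1, 2 and 3 lay nearer to their breed at 2 of 3, 6 of 8 and 6 of 6 loci. Macheng black 3 did so at 2 of 3. Pearson correlations of Macheng black 1 were 0.680, 0.630 and 0.641 with the Boer libraries and 0.662 and 0.627 with its own breed. The label therefore stays open. The circRNA at chromosome 24, 37557366 to 37576786, had 71 reads in Macheng black 1 and 0 in each Boer library. It passed the read filter only with Macheng black 1 counted, so it cannot serve as independent evidence for the label. A difference among Macheng black goats, such as in genotype, may also account for the low reads at the chromosome 17 locus and was not tested.

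The 3 libraries with the most back-splice reads, Boer 1, Boer 3 and Macheng black 2, set against the others gave 266 circRNAs listed in all of 1 side and none of the other, more than the 99 by breed. With every library thinned to 23480 reads, this split gave 87.7, so its excess may come from the read totals. The breeds gave 90.3, the most of the 10 splits. The thinned libraries were not fully equal, since Macheng black 3 was kept whole and the others lost circRNAs left with 1 read. Whether the breed count exceeds chance stays open with 10 splits.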
